A study of Mus musculus with 6 samples.

How the data were processed

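Gene expression was measured on 6 arrays in double-positive (DP) thymocytes of C57BL/6 mice aged 3 weeks, 3 arrays from wild-type (WT) mice and 3 from Hdac3 knockout (KO) mice. Groups and replicate numbers were taken from the sample titles. Total RNA was purified with a column kit and converted into biotin-labelled sense-strand target for an Affymetrix whole-transcript array, per the labels' protocols. RNA from 2 mice of each genotype was pooled, per the series' design text. The text counts 3 biological replicates and does not say which mice went into which array, so the p-values measure only the spread between these arrays, part of which may be technical. No scan date or other batch was given in the sources used here.

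The values used were the log2 probe set values deposited by the authors, 1 column per array. That they are log2 values was read from their range, from 1.94 to 13.98. The background correction, the normalization between arrays and the summary of probes into probe sets are not given in the sources used here. Array means differed little, between 5.99 and 6.01, while medians and interquartile ranges differed between arrays. The table held 28853 probe sets, and 701 of them shared their values on all 6 arrays with another probe set. Detection calls and background levels were not used here, so the signal at which a probe set rises above background is unknown and differences of dim probe sets are the least certain. The number of arrays limits the precision: the median standard error of a difference between genotypes was 0.11 on the log2 scale.

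Probe sets were named through the platform's gene annotation, with symbols checked by Entrez identifier against the RefSeq genes of mouse assembly GRCm38.p6. Of all probe sets, 21789 had 1 gene symbol, 1621 had several and 5443 had none. Of the probe sets with 1 symbol, 21698 matched by Entrez identifier and 0 symbols needed an update. A probe set with several symbols was tested and counted, and no gene was named from it. For 999 genes with several probe sets the one with the highest mean over all 6 arrays stood for the gene, which gave 19938 genes. The parts of each transcript that the probes cover were not analysed here.

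The 23410 probe sets with at least 1 gene were tested with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) in a model of the 2 group means. P-values were two-sided and adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. A further count required a change of at least 2-fold. Values are given as mean ± SD over 3 arrays, and log2 differences are KO minus WT with their standard error (SE). An exact test of 3 against 3 arrays cannot give a p under 0.1, so no single-gene permutation test was run.

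The genes named were set by a rule. They are Hdac3, and the 10 genes with the largest rise and the 10 with the largest fall among probe sets with 1 symbol, an adjusted p under 0.05, no overlap between the groups and a mean in the higher group above the median of all tested probe sets. Predicted genes, clones, small RNAs and receptor segments were counted but not named. Also named are up to 4 called members of each fixed gene list with the largest changes, or the 2 with the smallest p where none was called. Cd4, Cd8a, Rag1, Bcl2l1, Cd69, Cd5, Il7r and Ncor1 were among the genes to be given in any case. Ncor1 had no probe set paired with it alone and was not analysed here. Other named genes were chosen after their values were seen.

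The 28 gene lists held 460 different genes, and 46 of these had no probe set paired with them alone. A pair of genes was found under newer symbols, Scart1 as Cd163l1 and Faim3 as Fcmr. Lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation. Fry asked a different question, whether a list differed from no change. Members were counted at an adjusted p under 0.05 over all probe sets tested, and again when adjusted over the list alone.

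The groups, the model, the rule for named genes, the gene lists and the first set of alternatives were fixed before the data were examined. That set comprised quantile normalization, median centring, a filter on dim probe sets, tests over all probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array, and the mean of a gene's probe sets. Cyclic loess normalization, quantile normalization without KO array 2, quantile normalization with the filter on dim probe sets, and a plain equal-variance test per probe set were chosen after seeing the data. The fit was tested on simulated data with 200 of 23410 probe sets changed, in 20 draws. It recovered 52.4% of changes of 0.5 on the log2 scale, 99.6% of changes of 1 and 100% of changes of 2. On average 6.71% of its calls were false. In simulated data with no changed list, 0 of 28 lists were called, and a list lowered by 0.5 was called, in 1 draw. The simulated probe sets varied independently and had no level-dependent difference between arrays. In the real data the estimated correlation within the neutrophil list was 0.75. The simulated rates of false calls and list calls therefore do not carry over to correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.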

Results

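Expression was profiled in DP thymocytes, the precursors of T cells in the thymus that carry both the CD4 and the CD8 coreceptor. WT mice were set against mice labelled as knockouts of Hdac3, the histone deacetylase at the core of the NCoR/SMRT corepressor complexes. The labels name the knockout strain after Lck and Hdac3, and the deleted part of Hdac3 is not given in the sources used here. Each genotype had 3 arrays. Median log2 values were 5.50, 5.54 and 5.60 on the WT arrays and 5.60, 5.70 and 5.64 on the KO arrays. Pearson correlations across probe sets were 0.994 to 0.996 within a genotype and 0.985 to 0.993 between genotypes, where probe sets are not independent replicates. The first principal component held 53.5% of the variance and separated the genotypes. Its scores were -27.4, -22.3 and -7.57 on WT arrays 1 to 3 and 10.5, 30.6 and 16.2 on KO arrays 1 to 3. This order of the 6 arrays is that of their interquartile ranges, given next, so the component cannot tell genotype from the spread of signal.

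Signal was compressed on the KO arrays. Their interquartile ranges were 3.25, 3.06 and 3.18 on the log2 scale, against 3.49, 3.42 and 3.29 on the WT arrays. The median difference between genotypes therefore depended on signal level, from 0.16 in probe sets with a mean signal near 5.49 to -0.17 in those near 7.79, in 10 bins of equal size. After quantile normalization the medians of all 10 bins lay between -0.04 and 0.05.

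**Figure D1:**
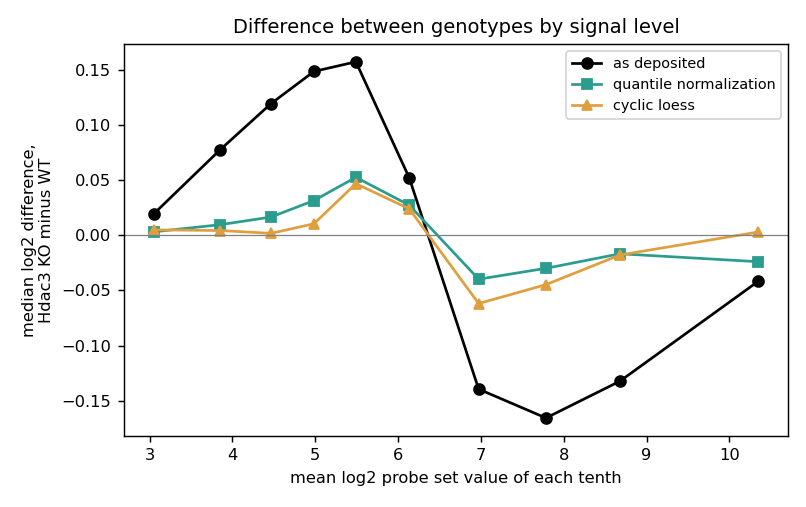
Median log2 difference between Hdac3 KO and WT (vertical axis) against the mean log2 probe set value (horizontal axis) for 10 equal bins of the 23410 probe sets. Points are medians over 2341 probe sets; in the deposited values they run from 0.16 to -0.17, and after quantile normalization from 0.05 to -0.04.

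The comparison asked how gene expression differs with the Hdac3 knockout in DP thymocytes. Hdac3 itself was lower on every KO array. Its probe set had a mean log2 value of 9.42 ± 0.02 (SD, n = 3) in WT and 8.31 ± 0.02 (SD, n = 3) in KO, a difference of -1.12 (SE 0.08) or 2.17-fold (limma, adjusted p = 3.5e-04). The KO signal was 46.2% of the WT signal (95% interval 40.5% to 52.6%). A probe set can hold probes outside the deleted part, so this level is not a measure of the remaining protein or of the share of cells that kept the gene.

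The genes that rose most encode an immune GTPase, cytokine and adhesion receptors and signalling proteins. Gimap7, of the GTPases of immunity-associated proteins, rose from 5.33 ± 0.09 to 8.09 ± 0.10, a log2 difference of 2.75 (SE 0.10, limma adjusted p = 3.2e-06). Il2ra, the alpha chain of the interleukin-2 receptor and a marker of the earlier double-negative stage, rose from 5.51 ± 0.64 to 7.79 ± 0.39 (log2 difference 2.28, SE 0.29, limma adjusted p = 0.0033). Spsb1, a substrate adaptor of ubiquitin ligases, rose by 2.13 and Itgam, the CD11b integrin chain common on myeloid cells, by 2.07. Rises of 1.57 were measured for both Myo1f, an unconventional myosin of blood cells, and Ankrd6, an ankyrin repeat protein of Wnt signalling. Rasgrp4, a Ras exchange factor, rose 2.83-fold, the tetraspanin Cd53 by 1.38 on the log2 scale, Gramd3 by 1.27 and the ERK phosphatase Dusp5 by 1.26. SEs of these last 8 genes were 0.09 to 0.15. All 10 were higher on each KO array than on any WT array, which the rule for naming required.

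The genes that fell most encode a transporter, surface proteins, junction and guidance proteins and enzymes of sulfur metabolism. Slc7a11, the cystine transporter, fell from 9.34 ± 0.35 to 6.57 ± 0.70, a log2 difference of -2.77 (SE 0.30, limma adjusted p = 0.0017). Ly6d, a lipid-anchored surface protein of lymphocytes, fell from 9.75 ± 0.35 to 7.40 ± 1.07 (log2 difference -2.35, SE 0.43, limma adjusted p = 0.015). Tdrd5, a tudor domain protein of germ cells, differed by -2.30, Jup, the junction protein plakoglobin, by -2.27, and Nrp1, a semaphorin and VEGF coreceptor, by -2.10. Il17rb, a receptor chain for interleukin-25, differed by -1.88. The sulfate donor synthase Papss2 and the mitochondrial sulfide oxidoreductase Sqor both differed by -1.86, the sulfatase Arsi by -1.78 and the membrane protein Itm2a by -1.65. SEs of the last 8 genes were 0.10 to 0.22. The groups did not overlap for any of the 10, again by the rule for naming. Ly6d was not called when WT array 1 was left out (log2 difference over the 6 leave-one-out fits -2.71 to -1.74, limma adjusted p up to 0.067) or with an intensity trend and robust prior (limma adjusted p = 0.12).

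**Figure D2:**
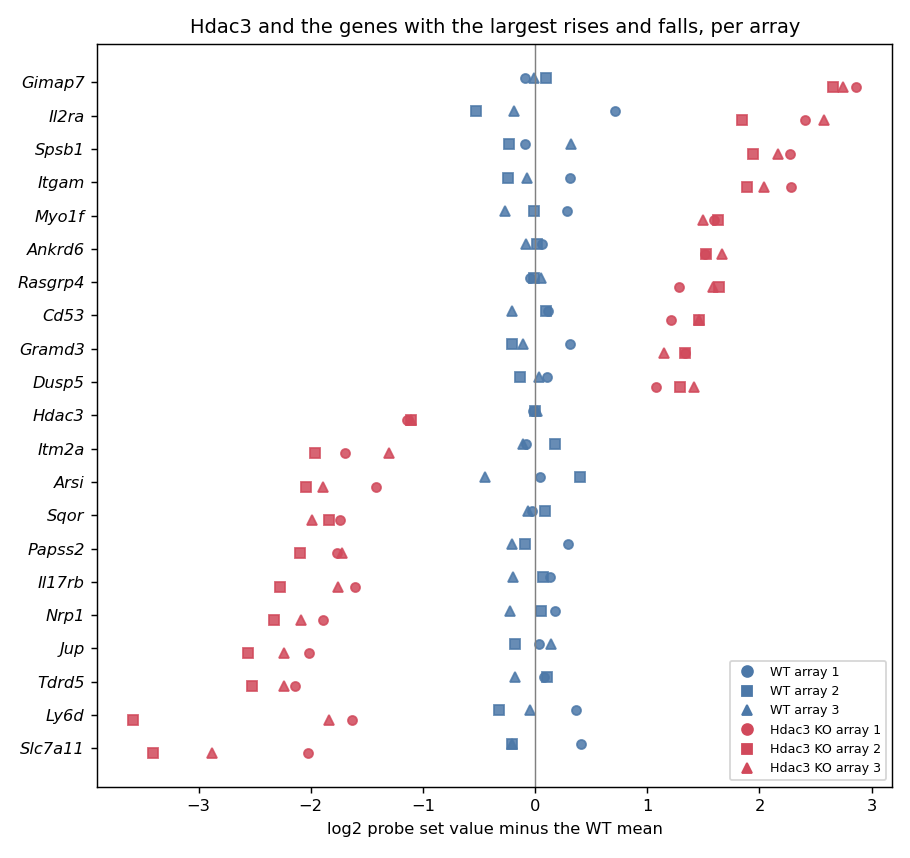
Log2 probe set value of each array minus the WT mean (horizontal axis) for Hdac3 and the 10 genes with the largest rises and falls (vertical axis). Blue symbols are the 3 WT arrays and red symbols the 3 Hdac3 KO arrays, with 1 shape per array number. Rises run up to 2.75 and falls down to -2.77 in the mean. No red symbol overlaps the blue ones of its gene, which the rule for naming required of all genes but Hdac3.

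Across all genes, 1355 of 23410 probe sets differed between the genotypes (limma, Benjamini-Hochberg adjusted p under 0.05), 409 higher and 946 lower in KO. They stood for 1214 genes, 367 higher and 847 lower. At least 2-fold changes were measured in 119 probe sets, 26 higher and 93 lower. The groups did not overlap for 7022 of the 23410 probe sets, where chance gives 10% for a single probe set. Every KO array had a smaller interquartile range than every WT array, so this count cannot tell genotype from compressed signal. Higher calls made up 30.2% of all calls, 35.0% after quantile normalization (328 higher, 608 lower), 41.4% after quantile normalization with dim probe sets left out (517 higher, 732 lower) and 9.56% after median centring (197 higher, 1863 lower), which moved the median difference of all probe sets from 0.02 to -0.08. The total count ranged from 474 without KO array 2 to 1946 without WT array 3, and was 517 without WT array 1, 505 without WT array 2, 826 without KO array 1 and 489 without KO array 3. Array quality weights gave 2285 calls and a plain equal-variance test per probe set 13, of which 7 were 2-fold.

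Genes that mark the DP stage differed little. Cd4 had log2 values of 11.23 ± 0.14 in WT and 11.23 ± 0.07 in KO (difference -0.00, 95% interval -0.23 to 0.23), Cd8a 12.85 ± 0.06 and 12.81 ± 0.04 (difference -0.04), and the recombinase gene Rag1 12.94 ± 0.06 and 13.01 ± 0.02 (difference 0.07). Bcl2l1, the survival gene of the DP stage, differed by -0.10 (95% interval -0.31 to 0.11). With 1 array left out, Cd4 ranged from -0.06 without WT array 3 to 0.07 without WT array 1, Cd8a from -0.07 without WT array 2 to -0.01 without WT array 1, Rag1 up to 0.10 without WT array 1, and Bcl2l1 from -0.15 without WT array 2 to -0.04 without WT array 1. Of 19 measured genes of the DP programme, Themis, a T cell selection adaptor, rose by 0.43, Cd1d1, which presents lipids to natural killer T cells, fell by 0.65 and 17 did not pass (adjusted over the list alone, 1 higher and 4 lower), and the list did not shift (camera, adjusted p = 0.26). Cd1d1 was not called when WT array 1 or 2 or KO array 2 or 3 was left out (difference -0.73 to -0.53, limma adjusted p up to 0.079). Themis was called in only 1 of the 6 leave-one-out fits, the one without WT array 1 (difference 0.36 to 0.53, limma adjusted p up to 0.14).

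Among genes of the preceding double-negative stage, Il2ra rose and Cd44, an adhesion receptor of early progenitors and activated T cells, fell by 0.66, while 17 of 19 did not pass (adjusted over the list alone, 2 higher and 1 lower). Of 17 genes of mature single-positive cells, Ikzf2, the transcription factor Helios, fell by 1.23 (SE 0.16) and Il7r, the interleukin-7 receptor chain, by 1.19 (SE 0.17, limma adjusted p = 0.0056). The other 15 did not pass, and the list-alone count was also 0 higher and 2 lower. Neither list shifted against the other genes (camera, adjusted p = 0.43 and 0.71).

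Among genes that T cell receptor (TCR) signals induce during positive selection, 9 of 20 fell, 1 rose and 10 did not pass (adjusted over the list alone, 10 lower and 2 higher). Their median log2 difference was -0.35, and the shift of the list passed with a preset correlation but not with an estimated one (camera, adjusted p = 0.0017 and adjusted p = 0.75 with an estimated correlation). Besides Itm2a, the falls were those of Slamf6, a surface receptor of the SLAM family (-0.97), the zinc finger factor Egr2 (-0.91), the inhibitor of E proteins Id3 (-0.90), the nuclear factor Tox (-0.90), Egr1 (-0.79), the orphan nuclear receptor Nr4a3 (-0.73), the EGR corepressor Nab2 (-0.68) and the adhesion receptor Cd2 (-0.49). Cd53 was the one that rose. Cd5 and Cd69, surface proteins that increase with TCR signal strength, had positive differences that did not pass, of 0.47 (95% interval 0.14 to 0.81, limma adjusted p = 0.093) and 0.35 (95% interval 0.03 to 0.68, limma adjusted p = 0.17). They were lowest at 0.31 for Cd5 without KO array 2 and 0.18 for Cd69 without WT array 3. Nr4a1 differed by -0.06 and Egr3 by -0.03, and neither passed.

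The shift at the preset correlation was also lost when dim probe sets were left out (camera, adjusted p = 0.18, with 8 of 18 members lower, and 0.11 after quantile normalization as well). The list's median difference was still -0.35 there, and -0.30 after quantile normalization as well, so the test against the remaining genes changed and not the size. Without KO array 2 the list had 6 members lower, as it had without WT array 1, and 5 after quantile normalization without KO array 2. On KO array 2 the median of 12 neutrophil markers lay 1.14 above the WT mean. Slamf6 was not called when WT array 1 or 2 or KO array 2 or 3 was left out (difference -1.21 to -0.81, limma adjusted p up to 0.089).

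**Figure D3:**
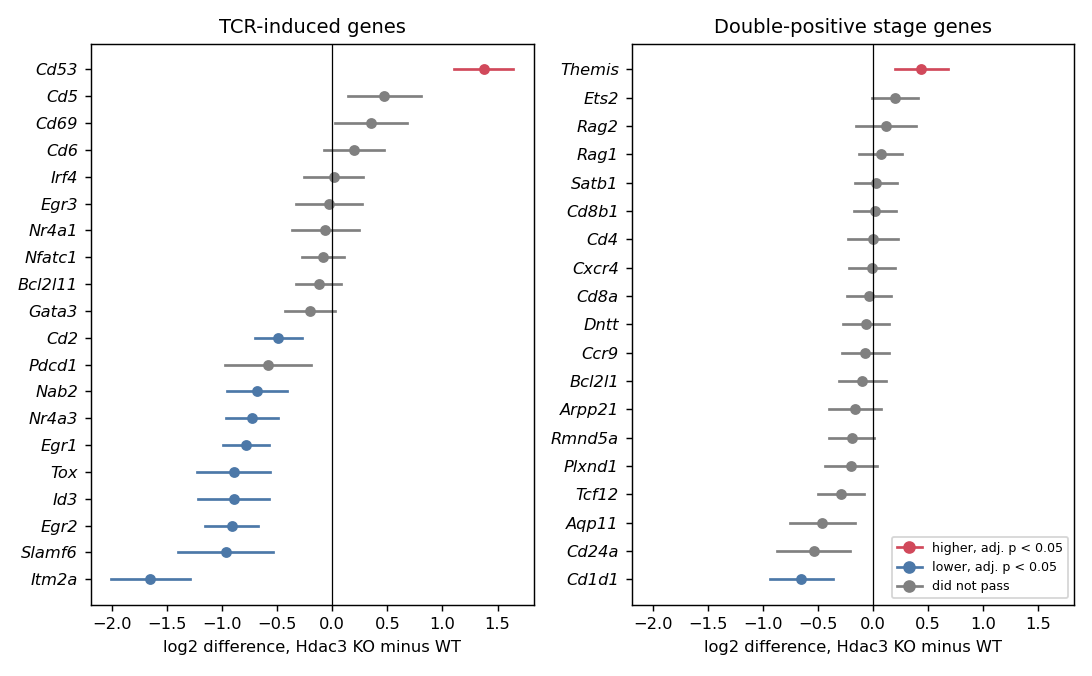
Log2 difference between Hdac3 KO and WT (horizontal axis) for the 20 TCR-induced genes of positive selection (left) and 19 genes of the DP stage (right). Points are limma estimates from 3 arrays per genotype and lines their 95% intervals; 9 genes on the left and 1 on the right fell at an adjusted p under 0.05, and 1 gene in each panel rose.

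Regulators of the T lineage fell in part. Of 20 measured T-lineage transcription factors, Id2 fell by 1.08, Id3 and Tox as above, and Lef1, a partner of beta-catenin, by 0.40, while none rose and 16 did not pass (adjusted over the list alone, 5 lower). Of 18 components of TCR signalling, the adaptors Grap2 and Tespa1 rose by 0.55 and 0.54 and the TCR zeta chain Cd247 fell by 0.43 (adjusted over the list alone, 4 higher and 1 lower). Their camera adjusted p were 0.10 and 0.18; the TCR signalling list passed upward after cyclic loess normalization (adjusted p = 0.022) and when dim probe sets (adjusted p = 0.019) or WT array 1 (adjusted p = 0.034) were left out, but not with an estimated correlation in the same settings (adjusted p = 0.81, 0.62 and 0.74 with an estimated correlation). Lef1 and Cd247 were called in only 1 of the 6 leave-one-out fits, that without WT array 3 (Lef1 -0.44 to -0.37, limma adjusted p up to 0.12; Cd247 -0.47 to -0.35, limma adjusted p up to 0.14). Tespa1 was not called when WT array 2 or any KO array was left out (0.41 to 0.62, limma adjusted p up to 0.11).

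Partners of HDAC3 were measured beside it. Of 18 genes of histone deacetylases and their corepressor complexes, Tbl1x and Tbl1xr1, which encode related WD40 subunits of NCoR/SMRT, rose by 0.75 (SE 0.10) and 0.66 (SE 0.09), and a further probe set of Tbl1xr1 gave 0.60 (SE 0.10, limma adjusted p = 0.011). Hdac5, a class IIa deacetylase, rose by 0.49, and its call was lost when WT array 2 or KO array 3 was left out (0.47 to 0.50, limma adjusted p up to 0.053). Hdac3 was the one that fell and 14 did not pass (adjusted over the list alone, 3 higher and 6 lower), with no shift of the list (camera, adjusted p = 0.56).

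Cell cycle genes did not move together. Of 29 measured, the cyclin Ccnd2 fell by 0.90, Ccnd3 rose by 0.40 and 27 did not pass (adjusted over the list alone, 1 higher and 1 lower). The CDK4 and CDK6 inhibitor Cdkn2c fell by 0.92, and 6 other CDK inhibitors did not pass (adjusted over the list alone, 2 higher and 2 lower). Among 18 p53 response genes Ei24, an endoplasmic reticulum protein, fell by 1.02 and 17 did not pass (adjusted over the list alone, 1 lower). Among 14 BCL2 family genes the BH3-only gene Bid fell by 0.47 and 13 did not pass (adjusted over the list alone, 2 higher and 1 lower). Camera adjusted p of these lists were 0.84, 0.89, 0.72 and 0.95. The cell cycle list had a positive median and a negative mean and test, the BCL2 list a negative median and test with a positive mean, and the p53 list a positive median and camera test with a negative fry test. Ccnd3 was called in only 1 of the 6 leave-one-out fits, that without WT array 3 (0.37 to 0.43, limma adjusted p up to 0.11), and Bid was not called without WT array 2 or KO array 2 or 3 (-0.49 to -0.45, limma adjusted p up to 0.066).

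Of 17 genes of LXR targets and fatty acid synthesis, the sterol exporter Abcg1 rose by 0.58, the elongase Elovl6 by 0.58 and the desaturase Scd2 by 0.56, Acaca, the acetyl-CoA carboxylase, fell by 0.52 and 13 did not pass (adjusted over the list alone, 4 higher and 1 lower). A further probe set of Acaca gave -0.45 and did not pass (limma adjusted p = 0.12). Mvd, an enzyme of the mevalonate pathway, rose by 0.76 and was the one of 18 cholesterol synthesis genes to pass (adjusted over the list alone, 1 higher and 2 lower). Nr1d2, the clock repressor REV-ERB beta, fell by 1.25 (SE 0.15), the one of 16 clock genes to pass (adjusted over the list alone, 2 lower). Of 15 glycolysis genes Tpi1 fell by 0.56 and Pfkl by 0.44 (adjusted over the list alone, 1 higher and 2 lower). None of these 4 lists shifted (camera, adjusted p = 0.72, 0.56, 0.43 and 0.56). Abcg1, Acaca and Tpi1 were called in only 1 of the 6 leave-one-out fits, that without WT array 3 (Abcg1 0.40 to 0.68, Acaca -0.60 to -0.39, Tpi1 -0.65 to -0.45), and Pfkl in only that without KO array 1 (-0.50 to -0.39), with limma adjusted p up to 0.13, 0.15, 0.12 and 0.12. Elovl6 was not called without KO array 2 or 3 (0.50 to 0.65, limma adjusted p up to 0.053).

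Cytokine receptor genes changed in both directions. Of 19 measured genes of cytokine receptors and their signalling, Il6st, the shared gp130 chain, fell by 0.82, as did Il7r (-1.19), while Il21r rose by 0.70 and Ifngr1 by 0.37 (adjusted over the list alone, 6 higher and 5 lower). The list's median was positive, its mean negative, and neither camera (adjusted p = 0.95) nor fry's test in 1 direction (adjusted p = 0.85) passed, with opposite signs. Fry's mixed test, for changes in either direction, passed (adjusted p = 6.8e-06). Of 20 innate-like and effector genes Prf1, perforin, rose by 0.67, and Cd44 and the granule protein Nkg7 fell, Nkg7 by 0.45 (adjusted over the list alone, 3 higher and 3 lower). Of 15 genes of purinergic and death receptors the ATP receptor P2rx7 rose by 0.74 and Tnfsf10, the death ligand TRAIL, fell by 0.76 (adjusted over the list alone, 4 higher and 2 lower). The immediate-early genes Fosb and Zfp36 rose by 0.50 and 0.49 and 13 of that list did not pass (adjusted over the list alone, 4 higher). None of 17 interferon-stimulated genes passed, with differences of -0.50 for Xaf1 and -0.38 for Ifit2 (limma adjusted p = 0.0501 and 0.0722; adjusted over the list alone, 1 lower), although Xaf1 was called without KO array 1 (-0.59) and after quantile, cyclic loess and median scaling, and Ifit2 without WT array 3 (-0.47) and after median centring. Camera gave adjusted p of 0.50, 0.56, 0.16 and 0.49 for the last 4 lists, and the immediate-early list passed when KO array 1 (adjusted p = 0.049) or dim probe sets (adjusted p = 0.026) were left out, but not with an estimated correlation there (adjusted p = 0.85 and 0.62 with an estimated correlation).

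Several of these calls were lost when 1 array was left out. Ifngr1, Nkg7 and Zfp36 were called in only the fit without WT array 3 (Ifngr1 0.36 to 0.40, Nkg7 -0.53 to -0.39, Zfp36 0.38 to 0.60), and Fosb in none of the 6 (0.41 to 0.57), with limma adjusted p up to 0.13, 0.13, 0.15 and 0.13. Il21r was not called without WT array 2 or KO array 3 (0.60 to 0.79, limma adjusted p up to 0.055), and Tnfsf10 not without KO array 2 or 3 (-0.87 to -0.59, limma adjusted p up to 0.078). Of the 65 called genes named by the rule, 40 kept their call in each of the 6 fits, and 25 lost it in at least 1. Genes named outside the rule, such as Egr1, Nr4a3, Nab2, Cd2, Alox5ap and the Gimap genes other than Gimap7, are not in this count. Signals of Il7r, Cd44, Nkg7, Fosb and Nr4a3 were dim, under the median of the tested probe sets (5.77) in both groups.

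Scaling also ended calls of named genes with small changes. Cd247, Bid, Acaca, Tpi1, Pfkl, Fosb and Klf1, which encodes an erythroid factor, were not called after quantile or cyclic loess normalization, Abcg1 not after quantile normalization and Themis not after cyclic loess normalization. Median centring ended the calls of Themis, Tespa1, Ccnd3, Abcg1, Ifngr1, Fosb, Zfp36, Klf1 and Cldn3, all of them rises. After quantile normalization without KO array 2, Tox, Ccnd2, Cdkn2c and Scd2 were not called either, with limma adjusted p up to 0.0791, and Epcam was not called with an intensity trend and robust prior.

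Most markers of other cell types did not pass. Of 12 neutrophil markers none passed the test on single genes (0 also when adjusted over the list alone), and the list shifted upward (camera, adjusted p = 0.023; adjusted p = 0.75 with an estimated correlation). Camp differed by 0.45 and Elane by 0.36. Most of the rise lay in 1 array: S100a8, S100a9, Lcn2, Ngp and Ltf, neutrophil granule and alarmin genes, were higher on KO array 2. There S100a8 had a log2 value of 7.12 against 4.36 to 5.02 on the other arrays. Elane was at 5.51 on both KO array 1 and KO array 2. Camp was at 5.51 on KO array 3 and 5.82 on KO array 2, against 4.97 to 5.22 on the WT arrays. Without KO array 2 the list's median difference was 0.10 (camera, adjusted p = 0.40). The shift was also lost without WT array 3 (adjusted p = 0.052), with array weights (adjusted p = 0.11) and after quantile normalization without KO array 2 (adjusted p = 0.79). Itgam, Myo1f, Rasgrp4 and Alox5ap, the last a leukotriene synthesis gene that rose as well (limma adjusted p = 0.0030), were higher on all 3 KO arrays, and Itgam lay 2.28, 1.89 and 2.04 above the WT mean.

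**Figure D4:**
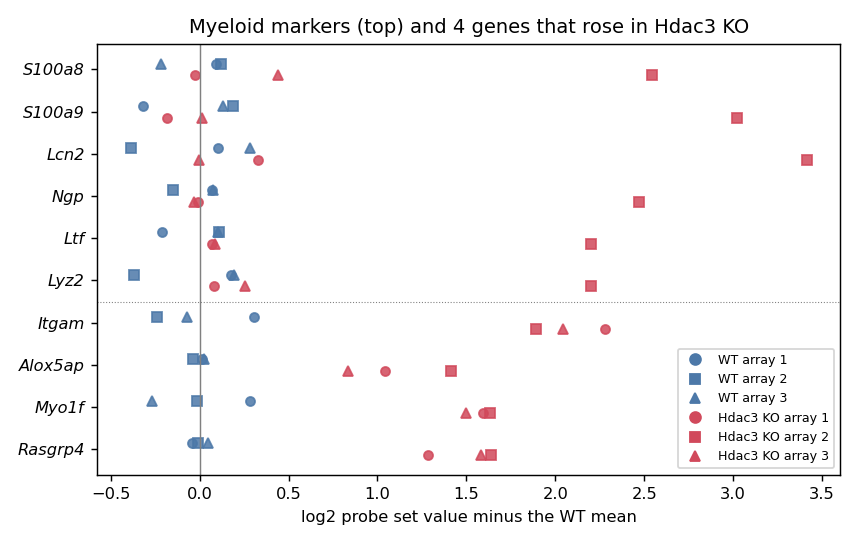
Log2 probe set value of each array minus the WT mean (horizontal axis) for 6 neutrophil or macrophage markers (above the dotted line) and 4 genes that rose in Hdac3 KO (below it). Blue symbols are the 3 WT arrays and red symbols the 3 Hdac3 KO arrays; the markers stand out on KO array 2 alone, where S100a8 reached 7.12, and the 4 genes are higher on every KO array.

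Of the remaining cell type lists none shifted (camera, adjusted p of 0.0695 to 0.792), although the 4 thymic epithelial genes left without dim probe sets did (adjusted p = 0.026, and adjusted p = 0.62 with an estimated correlation). Il18r1, a cytokine receptor chain of NK and innate lymphoid cells, rose by 1.48 (SE 0.16), and the other 9 genes of that list did not pass. Its signal was dim, 3.61 in WT and 5.09 in KO, against a median of 5.77 for the tested probe sets. Klf1 and Epcam, given below, were also under that median in both groups. In the gamma-delta T cell list, with 5 measured genes, the transcription factor Maf rose by 0.66 (adjusted over the list alone, 2 higher), and its call was lost without KO array 3 (0.55 to 0.76, limma adjusted p up to 0.056). Of 6 erythroid genes Klf1 rose by 0.44, and of 12 thymic epithelial genes the claudin Cldn3 rose by 0.47 and the adhesion molecule Epcam fell by 0.37, with the same counts when adjusted over the list alone, as for the NK list. No gene passed, in either count, among 11 B cell genes (Fcmr 0.35, Spib -0.33), 18 macrophage and dendritic cell genes (C1qa 0.39, Ctss -0.52) and 12 stromal and endothelial genes (Sparc 0.45, Pdgfra 0.37). Spib was at -0.17 without WT array 1 and -0.50 without WT array 2. C1qa was called without WT array 3 (0.29 to 0.48 over the 6 fits) and Ctss without WT array 2 (-0.70 to -0.35). Klf1 was not called without WT array 1 or 2 or KO array 2 or 3 (0.37 to 0.52, limma adjusted p up to 0.15), Cldn3 was called only without WT array 3 (0.38 to 0.58, limma adjusted p up to 0.14) and Epcam in none of the 6 fits (-0.41 to -0.34, limma adjusted p up to 0.13).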

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

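None of the tests in this part was chosen after its result was seen.

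Probe sets that the annotation pairs with no gene were left out of the main tests and are counted here from the test over all probe sets. Of these 5443 probe sets, 89 were higher in KO than in WT and 75 were lower (limma, Benjamini-Hochberg adjusted p under 0.05), 3.01% in all, against 4.49% of the probe sets paired with a gene when all are adjusted together. Their largest fall was -2.78 on the log2 scale. The median signal was 4.92, against 5.77 for paired probe sets. No explanation was tested.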

How the results depend on the processing

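Cyclic loess normalization, quantile normalization without KO array 2, quantile normalization with dim probe sets left out, and the plain equal-variance test were chosen after seeing the data. The Hdac3 fall passed under every alternative (-1.22 after median centring, -1.01 after quantile normalization). Numbers of changed probe sets (1355, with 409 higher and 946 lower) were, with higher and lower calls in turn, 2060 (197 and 1863) after median centring, 2285 (778 and 1507) with array weights, 437 (150 and 287) after quantile normalization without KO array 2, and 13 (8 and 5) in the plain test. Quantile normalization gave 936, with 328 higher and 608 lower. Leaving out 1 array gave 474 to 1946 calls, 114 to 651 higher and 345 to 1295 lower. For these changes the cause was not tested. The 119 changes of at least 2-fold stayed within 1.5 times that number, except for 7 in the plain test. The 2 shifted lists became 1 with array weights and after quantile normalization without KO array 2, 3 after cyclic loess normalization, 1 to 3 when an array was left out, and 0 with an estimated correlation and after quantile normalization with dim probe sets left out. Fry, which tests lists for a shift in 1 direction against no change and not against other genes, called 1. Its mixed test, for changes in either direction, passed for many lists that the test in 1 direction did not call. With dim probe sets left out alone 3 other lists passed, all lost with an estimated correlation (adjusted p = 0.62 each), while the neutrophil list had 0 members left. The 9 falls of TCR-induced genes were 5 after quantile normalization without KO array 2 and 6 to 10 when an array was left out. Of the 65 called genes named by the rule, 57 kept their call after quantile normalization, 56 after median centring and 57 after cyclic loess normalization. The number was 63 with an intensity trend and robust prior, 65 with array weights, 41 to 61 when an array was left out and 6 in the plain test. None of the 65 genes changed direction. Some lists that did not pass changed direction under an alternative, such as those of cholesterol synthesis, the cell cycle and the BCL2 family after quantile normalization and that of the DP programme with dim probe sets left out, and none of these passed there. With the replicate number as a block 1162 probe sets were called (344 higher, 818 lower) and 54 named genes kept their call. Deviations of same-numbered arrays correlated at 0.25, -0.07 and -0.03, and those of differently numbered arrays at -0.34 to 0.32. So few values cannot decide whether the numbers pair the arrays. Without detection calls, the level at which signal falls into background remains unknown.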

Other observations

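The tests of gene families, of the excess of lower calls, of Itgam and its companions, of the level-matched neutrophil lists and of the TCR-induced list were chosen after the result was seen. The sulfur list was chosen after 4 of its genes were seen among the largest falls.

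The Gimap genes, a family of GTPases of lymphocytes, rose as a family. Besides Gimap7 (2.75), the rises were Gimap4 1.13, Gimap3 0.95, Gimap8 0.85, Gimap6 0.75 and Gimap9 0.71 on the log2 scale, while Gimap1 (0.11) and Gimap5 (0.11) did not pass. All 8 differences stayed positive and the same 6 passed after quantile normalization, where Gimap5 was at 0.00. Over 593 symbol families tested in each direction, this was the 1 that passed Fisher's exact test in both the deposited and the quantile-normalized values (6 of 8 members, Benjamini-Hochberg adjusted p = 1.2e-06). These genes are related in sequence and lie together in the genome, so their probe sets are not independent.

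Slc7a11, Papss2, Sqor and Arsi all handle sulfur compounds. Among 30 other measured genes of sulfur and cysteine metabolism, Gclm, the modifier of glutathione synthesis (-0.68), Slc3a2, the partner chain of Slc7a11 (-0.49), the sulfate transporter Slc26a2 (-0.49) and the sulfotransferase Ndst2 (-0.48) fell, the sulfatase Arsg rose by 0.36 and 25 did not pass. The median was -0.07 (95% bootstrap interval over genes -0.16 to 0.05), and camera found no shift (two-sided p = 0.133, n = 30 genes; 0.508 after quantile normalization). A wider fall of the pathway thus stays open.

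Neighbouring genes were called in the same direction more often than shuffled calls. With like symbols left out, 83 adjacent pairs of called genes shared a direction, against a median of 47 in 10000 shuffles within levels of signal (permutation test, p = 1e-04, the smallest the shuffles can give). After quantile normalization there were 46 against 20. Overlapping genes explain few of them, since 75 pairs remained without overlaps. The shuffles moved calls between genes, not arrays between genotypes, and ignored correlation between neighbouring genes. Their p therefore does not measure the spread between arrays and cannot tie the pairs to genotype. Among the 100 measured neighbours of Hdac3 itself, 3 were called, 0.491 times the share of all genes (Fisher's exact test, two-sided, p = 0.29). Calls thus showed no excess near Hdac3. The neighbours were not matched on signal level, on which the share of calls depended. Whether alleles of another strain were carried along with the Hdac3 allele therefore stays open.

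More probe sets were lower than higher in KO. If the compressed signal of the KO arrays were the whole cause, calls would be balanced once the arrays shared a distribution, but 35.0% were higher after quantile normalization and 35.1% after cyclic loess normalization, or 41.4% with dim probe sets left out as well. Lower calls dropped from 946 to 608 after quantile normalization, so the compression may account for part of the excess. The excess depended on signal level. In the bin with a mean signal near 6.97, 52 calls were higher and 247 lower, and in the brightest bin 67 and 58. After quantile normalization the median difference of the bin near 6.97 was still -0.04. A loss of expression that follows from the Hdac3 knockout remains open. The compression went with genotype, so these counts cannot tell the share of each. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 1355 calls and 119 of at least 2-fold, the highest other split 1 and 1. In each case 1 of 10 splits gave as many. Each other split mixes the genotypes, so a genotype effect adds to the spread within its groups and lowers its count.

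Itgam, Alox5ap, Myo1f and Rasgrp4 are known from myeloid cells, and neutrophil genes were high on KO array 2. Neutrophils as the source of these 4 rises are argued against by KO arrays 1 and 3, where the markers' median difference from the WT mean was at most 0.0776 while each of the 4 lay at least 0.84 above it. Whether neutrophil transcripts entered KO array 2 stayed undecided by the test set beforehand, since 16 further myeloid genes lay 0.384 above the other 5 arrays in the median, between the bounds of 0.2 and 0.5. All 12 listed markers and 13 of the further genes were highest there, Elane only at 5.511 against 5.507 on KO array 1. After quantile normalization 11 of 12 and 8 of 16 were highest there, with the median of the further genes at 0.249. Of all genes, 26.4% were highest on KO array 2 in the deposited values and 22.5% after quantile normalization. In a comparison chosen afterwards, the further genes lay at percentile 99.99 and the 12 markers at percentile 100 of 10000 lists matched on signal, which argues against a rise of all dim probe sets. The matched lists ignored correlation between genes, so these percentiles are not p-values.

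Of the TCR-induced genes of positive selection 9 of 20 fell, while the shift of the list was lost with an estimated correlation (camera, adjusted p = 0.75) and without dim probe sets (camera, adjusted p = 0.18). Without dim probe sets the list's median difference was still -0.35. List medians of at most -0.261 after quantile and cyclic loess normalization argue against level-dependent compression as the whole cause of the members' falls. Of 10000 lists matched on signal, 0 lay as low in the deposited and in the quantile-normalized values. The matched lists ignored correlation between genes, and the list was examined because it had shifted, so that share is not a p-value. In the deposited values the matched lists had a median of -0.08, so compression may account for part of the falls. A lower share of selected cells would lower Cd69 and Cd5 too and stays open: over 4 scalings and the 6 fits with 1 array left out, the 95% interval of Cd5 lay above 0 in 10 of 10, that of Cd69 in 6 of 10, with a lowest bound of -0.0898. A fall of part of this programme that follows from the Hdac3 knockout stays open as well. The real split gave 2 shifted lists, the highest other split 5, and 9 of 10 splits gave as many. Each other split holds both genotypes in unequal number in each group and so keeps part of the genotype contrast. These counts thus cannot tell whether list calls at the preset correlation follow genotype or other structure of these arrays. The 10 splits are also too few for a share under 0.05.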
